A study of Mus musculus with 8 samples.

How the data were processed

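Whole hearts of mice were profiled by RNA sequencing after 4 weeks of transverse aortic constriction (TAC), an operation that narrows the aorta and loads the left ventricle with pressure. Per the labels' protocols, RNA was extracted with Trizol and stranded mRNA libraries were made by BGI for DNBSEQ sequencing. The samples were 4 libraries from mice carrying the S727A form of STAT3, in which a phosphorylated serine is replaced by alanine, and 4 from wild-type mice (WT). All are assigned to a single batch in the labels, which name no sex and no animal behind a library, so p-values measure the spread between these libraries. Groups and replicate numbers came from the sample titles.

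The submitters' processing notes name FastQC, HISAT2, Bowtie2 and the mouse genome build GRCm38.p6, with no versions or roles. The counting tool is not given in the sources used here. A single deposited table held an estimated count per gene and library, per the file headers and values: 6.06% to 7.62% of the entries in a library were not whole, with a tolerance of 1e-06. It also held FPKM values made by the authors, per the file headers, which divide by gene length and library size. The same table held the authors' group averages, which equalled the plain means of the 4 columns of each group. Its log2 ratio of S727A over WT and its p-value and q-value per gene were computed by the authors with a tool not given in the sources used here. Every column of per-sample values was matched to a sample by its name. The table listed 17191 genes, of which 17044 were annotated as mRNA. In 24 rows the symbol had been turned into a calendar date, and 3 symbols occurred more than once, so these rows were kept under symbol and identifier and none of them is named here. Genes of the mitochondrial genome were not analysed here. How reads shared between near-identical genes were divided is not given in the sources used here, so values of such families (hemoglobin and MHC genes) are uncertain.

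The estimated counts were rounded to whole numbers. Genes were kept by the edgeR filterByExpr defaults (minimum count 10, minimum total 15), which left 12998. The main comparison used edgeR 4.0.16 in R 4.3.3 with TMM normalization, robust dispersion estimation and the quasi-likelihood F test in legacy mode, two-sided, with the genotype as the only term. Calls were made at a Benjamini-Hochberg adjusted p under 0.05, and standard errors of log2 fold changes were taken from the F statistic. CPM values used TMM-scaled library sizes, and log2 CPM a prior count of 2. Total counts ran from 10577619 to 13305124 per library. All pairs of the 8 libraries were compared by chi-square over genes with at least 20 counts in a pair: the statistic per degree of freedom was 9.13 to 39, so no library repeated another.

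Gene lists for cardiac programs and for cell types that a whole heart can hold were written before the data were examined. The 28 lists with at least 5 tested members were compared with all other genes by limma camera (limma 3.58.1) on log2 CPM with a preset correlation between genes of 0.01, two-sided, and adjusted over the lists. The same test with an estimated correlation, limma fry and an exact two-sided permutation of each list's mean over all assignments of the libraries, the last added after seeing the data, were run beside it. Lists with fewer tested members were read as counts only.

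The genes named were set by a rule fixed before the data were examined. Stat3, Sptbn4, Nppa, Nppb, Myh6, Myh7, Acta1, Col1a1, Col3a1 and Postn were always named. To these came up to 10 genes per direction with adjusted p under 0.05, mean log2 CPM of at least 1, an established symbol and all libraries of a group on the same side of the other, taken by size of change. Had fewer than 5 passed in a direction, 5 more of smallest p would have been named as not passing. From each list up to 4 members past the threshold were named, or, where none passed, the 2 of smallest unadjusted p, as values. Genes named outside the rule are said to be so, and 1 gene that the rule takes is not reported here.

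Alternatives set before the data were examined were RLE normalization, no filter, a stricter filter (CPM of at least 1 in at least 4 libraries), DESeq2 1.42.0, limma voom, the other quasi-likelihood mode of edgeR, the replicate number as a block, each library left out in turn, an atrial marker covariate, a Y-linked expression covariate, removal of red-cell genes, and limma trend on log2 of FPKM with a pseudocount of 1. Added after seeing the data were a robust form of voom, DESeq2 filtering at 0.05, per-library offsets for transcript length and GC content, the exact permutation of list means, and fits without libraries that lacked Y-linked reads or held airway transcripts. Transcript lengths, GC contents and gene coordinates came from GENCODE M21 on GRCm38, with a length for 98.66% of tested genes.

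The procedure was tested on simulated data made from the means, depths and dispersions of these 8 libraries over the 12998 genes, in 3 runs with 200 changed genes each. It recovered 39.8% of genes changed 1.5-fold, 75.62% of those changed 2-fold and 95.45% of those changed 4-fold, and 5.61% of its calls were unchanged genes.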

Results

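The mRNA of whole hearts was measured after 4 weeks of TAC in 4 libraries from STAT3 S727A mice and 4 from WT mice. The question was how loss of this phosphorylation site alters the cardiac transcriptome under pressure overload, in a study of the complex that STAT3 forms with βIV-spectrin. Total counts were 13113671, 12816272, 11255599 and 12722952 in S727A libraries 1 to 4 and 10577619, 10764669, 13305124 and 12608764 in WT libraries 1 to 4. The first principal component of log2 CPM held 38.8% of the variance. It placed S727A 1 to 3 between -26.8 and -22.57 and WT 1 and 2 at 30.73 and 30.5, with S727A 4 at 2.31, WT 3 at -0.3 and WT 4 at 12.56 between them. Y-linked genes (Ddx3y, Eif2s3y, Kdm5d and Uty) summed to 9 counts in S727A 4 and 6 in WT 4, against 1940 to 2225 in each of the other libraries, so each group held 1 library almost without Y-linked reads.

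Stat3 itself (gene 20848, chromosome 11, 100885098 to 100939540, minus strand, GRCm38), the mutated gene, was at 164 ± 6.74 CPM in S727A and 201 ± 23.2 CPM in WT (mean ± SD, n = 4 each). All 4 S727A libraries lay below all 4 WT libraries, with a log2 fold change of -0.29 ± 0.09 (SE), and the difference did not pass the test (edgeR adjusted p = 0.155). The mutation changes a codon and need not alter the transcript level, so this value is no check of the labels. Sptbn4, which encodes βIV-spectrin (gene 80297, chromosome 7, 27356383 to 27447686), was near the detection limit at 1.049 ± 0.43 CPM in S727A and 1.497 ± 0.54 CPM in WT (SD, n = 4), with a log2 fold change of -0.50 ± 0.37 (SE, edgeR adjusted p = 0.504).

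Genes were then compared singly between genotypes. In S727A hearts 6 genes rose and 13 fell. The largest rise was in Jchain, the joining chain of polymeric immunoglobulins, at 10.3 ± 4.65 CPM in S727A against 0.72 ± 0.51 CPM in WT (SD, n = 4), a log2 fold change of 3.83 ± 0.50 (SE, edgeR adjusted p = 0.0287). Acbd4, an acyl-CoA-binding protein, rose by 0.78 ± 0.11 on the log2 scale, the zinc finger gene Zfp697 by 0.72 ± 0.11, Il18bp, a secreted inhibitor of interleukin 18, by 0.65 ± 0.11, and Smpx, a small protein of striated muscle, by 0.61 ± 0.09 (SE). Smpx was the most abundant of them at 299 ± 32.8 CPM against 196 ± 6.77 CPM (SD, n = 4). Capn6, a calpain family member at 1.71 against 0.47 CPM, also rose, but its mean expression kept it outside the rule and it is named after its values were seen.

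Among the genes that fell, Cbr2, a carbonyl reductase, dropped from 39.7 ± 10.3 CPM in WT to 13.9 ± 2.96 CPM in S727A (SD, n = 4), a log2 fold change of -1.52 ± 0.20 (SE, edgeR adjusted p = 0.0265). Armh4 followed with -1.38 ± 0.16, Cdh4, which encodes a classical cadherin, with -1.24 ± 0.20, and the extracellular hemicentin gene Hmcn2 with -1.14 ± 0.14 (SE). Mlxipl, a glucose-responsive transcription factor gene, had a log2 fold change of -0.98 ± 0.13 and Ctsc, encoding the lysosomal protease cathepsin C, one of -0.88 ± 0.11 (SE). The remaining log2 fold changes within the rule were -0.72 for Sfr1, a DNA repair gene, -0.62 for Mapt, which encodes tau, -0.62 for the butyrophilin-like gene Btnl9 and -0.61 for the adrenergic receptor gene Adra1a. Outside it, and chosen after their values were seen, were Kmt2d, a histone methyltransferase gene (-0.60), the hepcidin gene Hamp (-2.37, 0.54 against 2.86 CPM) and 2210407C18Rik (-1.94). Adjusted p in edgeR ran from 0.0234 to 0.0439 over all 19 genes, and each separated all libraries of the groups.

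**Figure D1:**
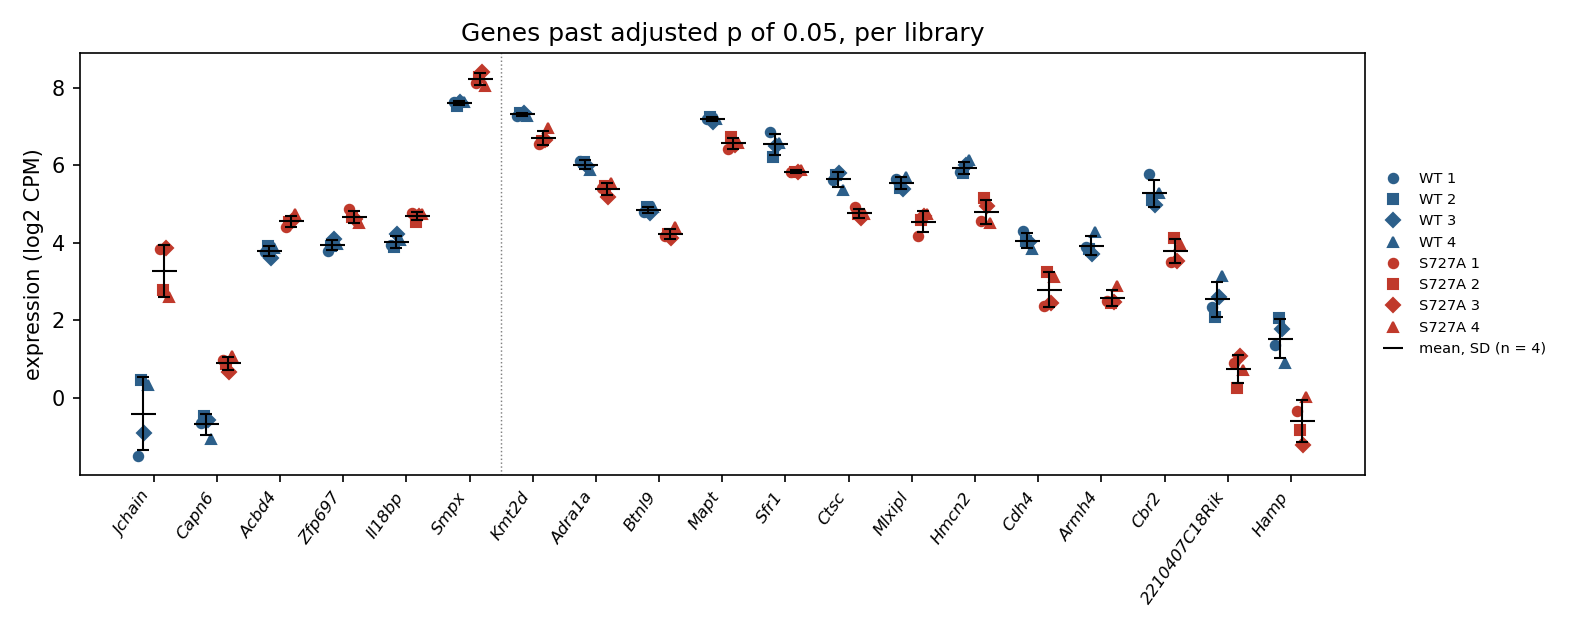
Expression (log2 CPM) of the 19 genes past an adjusted p of 0.05, ordered by log2 fold change from Jchain (3.83) to Hamp (-2.37), with each marker a library and black bars the mean and SD of 4 libraries. The 6 genes left of the dotted line were higher in all S727A libraries (red) than in all WT libraries (blue), and the 13 to its right were lower.

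Of the 12998 genes tested, 2308 had an unadjusted p under 0.05 in edgeR (17.76%), and 529 lay higher and 567 lower in all S727A than in all WT libraries, together 8.43% where chance gives 2.86%. The number of calls depended on single libraries: edgeR called 0 genes without S727A 1, S727A 3 or WT 1, 2 without WT 4 and 8 without S727A 2, but 275 without WT 3 and 617 without S727A 4. DESeq2 called 273 genes higher and 240 lower and limma voom 0 and 6, while the authors' deposited table lists 236 higher and 212 lower at q under 0.05, including all 19 genes above.

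Of the 19 called genes, 5 lie on chromosome 11, which holds 8.36% of tested genes with known coordinates (a difference that was not tested), and Acbd4 (103101682 to 103112200) and Mapt (104231390 to 104332090) lie within 5 Mb of Stat3. Within 2 Mb of Stat3, 15 of 84 other genes (17.86%) had an unadjusted p under 0.01, 8 higher and 7 lower, against 6.03% of all other tested genes (Fisher's exact test, two-sided p = 0.000152). From 2 to 5 Mb the share was 11.54% (9 of 78), and beyond 20 Mb on the same chromosome 5.66% (34 of 601). These distances and the cut-off were chosen after the data were seen. Fisher's test treats genes measured in the same 8 libraries as independent, so its p does not measure the spread between libraries.

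**Figure D2:**
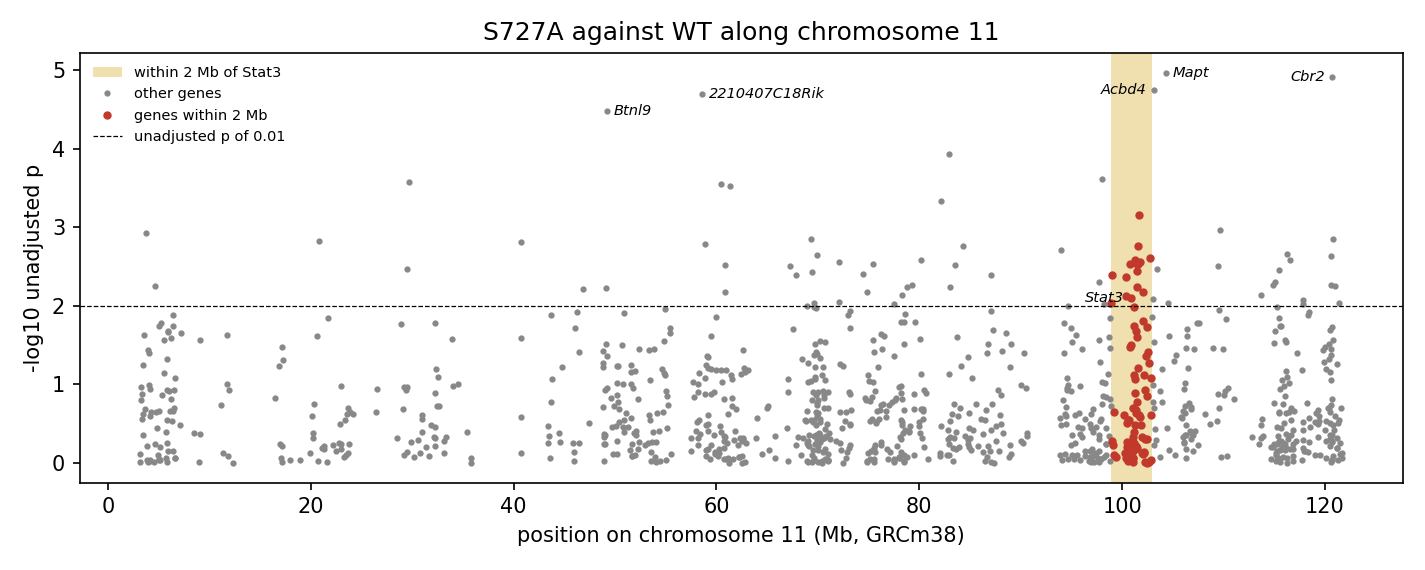
Unadjusted p of the edgeR comparison (-log10) against gene position on chromosome 11 (Mb, GRCm38), 1 point per tested gene, with the band marking 2 Mb either side of Stat3 and the dashed line an unadjusted p of 0.01. In the band 15 of the 84 red points, Stat3 aside, lie above the line, and the 5 called genes are named with Stat3.

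Gene lists fixed beforehand were next compared with all other genes. In limma camera 17 of 28 lists passed, 10 higher and 7 lower in S727A. With an estimated correlation between genes none passed, with adjusted p from 0.469 to 0.986 over the lists, and no list member passed the test over all genes. The exact permutation p of a list mean can be no smaller than 0.0286, and adjusted over the lists none was under 0.178. Each rise or fall of a list below is a camera call with this limit. Some lists share members, so their calls are not independent.

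Genes that mark pathological hypertrophy rose as a list, with a median log2 fold change of 0.80, and 18 of 19 members had a fold above 0 (camera adjusted p = 6.83e-07, 0.469 with an estimated correlation). Adjusted over the list alone, 10 members passed as higher. Csrp3, a muscle LIM protein gene, had a log2 fold change of 0.58 ± 0.12 and Xirp1 one of 0.47 ± 0.13 (SE). The natriuretic peptide gene Nppb was at 891 ± 316 CPM in S727A and 349 ± 176 CPM in WT (SD, n = 4), with a log2 fold change of 1.35 ± 0.47 (SE, edgeR adjusted p = 0.214). Nppa (0.89 ± 0.50), the fetal myosin gene Myh7 (0.85 ± 0.63) and skeletal actin Acta1 (0.52 ± 0.73) did not pass either, with edgeR adjusted p of 0.398, 0.527 and 0.754. The list mean was 8.93 ± 0.25 log2 CPM in S727A and 8.21 ± 0.33 in WT (SD, n = 4), and WT 3 at 8.69 lay above S727A 4 at 8.62 (exact permutation p = 0.0571).

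Extracellular matrix and fibrosis genes rose as a list with a median log2 fold change of 0.64, 35 of 37 members having a fold above 0 (camera adjusted p = 2.64e-11, 0.469 with an estimated correlation), and 0 passed when adjusted over the list alone. Log2 fold changes were 0.75 ± 0.19 for the metalloproteinase gene Mmp14 and 1.60 ± 0.48 for Timp1, a metalloproteinase inhibitor gene (SE). They were 0.63 ± 0.22 for Col1a1, 0.62 ± 0.20 for Col3a1 and 0.94 ± 0.42 for Postn (SE), whose edgeR adjusted p were 0.20, 0.173 and 0.297. WT 3, at a list mean of 6.41 log2 CPM, was close to S727A 1 to 3 (6.52 to 6.60), and S727A 4 was at 5.91. Cell-cycle genes had the largest list median, 1.30 (camera adjusted p = 5.42e-15, 0.469 with an estimated correlation). Of 26 members 25 had a fold above 0, and 17 passed as higher when adjusted over the list alone. Rrm2, a subunit of ribonucleotide reductase, was at 11.4 ± 6.01 CPM in S727A against 2.83 ± 0.71 CPM in WT (SD, n = 4), and Mcm5, of the replicative helicase, had a log2 fold change of 1.01 ± 0.22 (SE). Neither Rrm2 nor Mcm5 passed over all genes (edgeR adjusted p of 0.0863 and 0.0982).

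Immediate-early genes rose as a list (median 1.09, all 20 members with a fold above 0, camera adjusted p = 1.05e-07), as did ERK feedback genes (median 0.58, 13 of 15 above 0, camera adjusted p = 7.21e-06), both with an adjusted p of 0.469 with an estimated correlation. The immediate-early list mean differed by 0.971 log2 CPM, and by 0.61 without S727A 3 (6.06), while S727A 4 lay below WT 3 (4.26) and WT 4 (4.34). Adjusted over the list alone, 1 immediate-early and 10 ERK feedback genes passed. Egr3 had a log2 fold change of 1.34 ± 0.28, Jun of 0.36 ± 0.12, Etv4 of 1.17 ± 0.31 and the feedback inhibitor Spry1 of 0.84 ± 0.23 (SE). The ERK feedback list alone had all 4 S727A means above all 4 WT means (4.64 ± 0.27 against 4.06 ± 0.17 log2 CPM, SD, n = 4, exact permutation p = 0.0286). Known STAT3 target genes rose with a median of 0.35 (22 of 28 above 0, camera adjusted p = 0.0288, 0.549 with an estimated correlation), and 0 passed when adjusted over the list alone. Besides Stat3, the member of smallest p was Hif1a (0.37 ± 0.11, SE). The STAT3 target list shares members with the immediate-early, ERK feedback, hypertrophy and matrix lists. Immediate-early and ERK feedback genes also overlap. The camera call of STAT3 targets ended without S727A 1 (adjusted p = 0.108), S727A 2 (0.0653), WT 1 (0.0869) or WT 2 (0.0923), without WT 1 and WT 4 together (0.0766) and with the atrial marker covariate (0.0826).

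**Figure D3:**
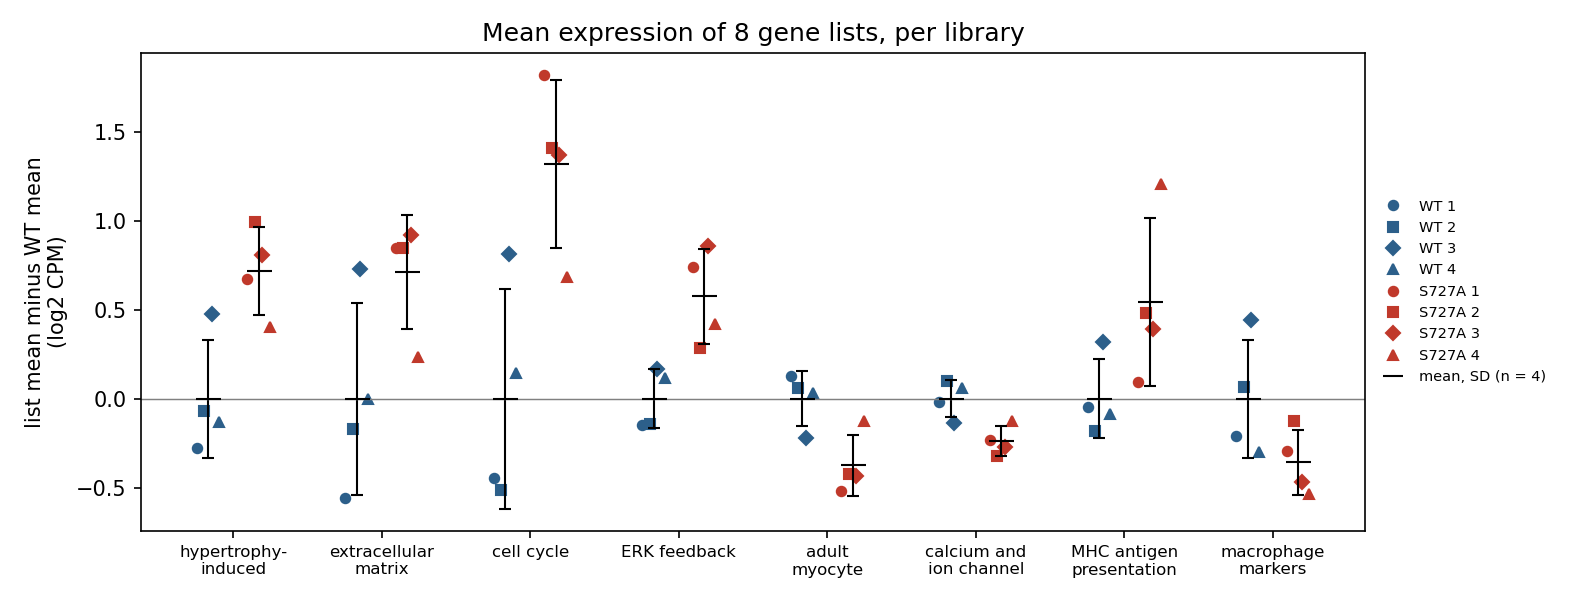
Mean log2 CPM of the members of 8 gene lists in each library, less the WT mean of that list, with markers for libraries and black bars for the mean and SD of 4 libraries. WT 3 (blue diamond) and S727A 4 (red triangle) lie between the remaining WT and the remaining S727A libraries in the hypertrophy, matrix and cell-cycle lists, and S727A 4 is highest for MHC genes.

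Antigen presentation genes of the major histocompatibility complex rose (median 0.64, all 18 members above 0, camera adjusted p = 3.06e-07, 0.469 with an estimated correlation), with 4 passing as higher when adjusted over the list alone. H2-Ab1 had a log2 fold change of 0.74 ± 0.19 and H2-Eb1 of 0.77 ± 0.21 (SE), and S727A 4 had the highest list mean at 5.97 log2 CPM. The list mean differed by 0.545 log2 CPM, and by 0.324 without S727A 4, and WT 3 (5.08) lay above S727A 1 (4.86). Interferon-stimulated genes did not pass (median -0.04, 12 of 27 above 0, camera adjusted p = 0.171), but passed as lower without S727A 4 (camera adjusted p = 0.000135), WT 1 (0.0493), both libraries lacking Y-linked reads (0.00034) or both WT libraries with airway transcripts (0.0429). Their members of smallest p were Oas2 (-0.79 ± 0.22) and Ifi27l2a (-0.43 ± 0.14, SE).

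Genes of the adult myocyte fell as a list (median -0.24, 17 of 20 below 0, camera adjusted p = 0.000194, 0.469 with an estimated correlation), and 4 passed as lower when adjusted over the list alone. Kcnv2, a potassium channel subunit gene, had a log2 fold change of -1.42 ± 0.26 and Atp2a2, the calcium pump of the sarcoplasmic reticulum, of -0.47 ± 0.11 (SE). Myh6, the adult myosin, had one of -0.27 ± 0.17 (SE, edgeR adjusted p = 0.429). Calcium-handling and ion channel genes fell (median -0.25, 25 of 34 below 0, camera adjusted p = 0.000724, 0.469 with an estimated correlation), with 7 lower and 1 higher when adjusted over the list alone. In that list the pacemaker channel gene Hcn2 was at -0.56 ± 0.13 while Casq2, the calcium store protein, was at 0.51 ± 0.11 (log2 fold change, SE). WT 3 lay below S727A 4 in both list means. The values were 8.34 and 8.43 log2 CPM for adult myocyte genes and 6.896 and 6.907 for calcium and channel genes. Sarcomere genes passed in the other direction by a small amount (median 0.09, 18 of 27 above 0, camera adjusted p = 0.0423, 0.549 with an estimated correlation), led by Synpo2l (0.96 ± 0.22) and Myom2 (0.55 ± 0.15, SE), which both passed when adjusted over the list alone. The sarcomere call ended without S727A 1, 2 or 3 (camera adjusted p of 0.0811, 0.0653 and 0.0571), WT 3 (0.149) or WT 4 (0.339), with the atrial marker covariate (0.0754) and with offsets for transcript length and GC content (0.0863). It also ended without both libraries lacking Y-linked reads (0.10) and without both WT libraries with airway transcripts (0.262). Spectrin and intercalated disc genes, the compartment of βIV-spectrin, did not pass (median -0.03, 12 of 28 above 0, camera adjusted p = 0.315). Ank2 was at -0.53 ± 0.15 and Pkp2 at 0.29 ± 0.10 (SE).

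Fatty acid oxidation genes fell (median -0.13, 27 of 32 below 0, camera adjusted p = 0.00222, 0.549 with an estimated correlation), with Acsl1 at -0.43 ± 0.13 and Cpt2 at -0.46 ± 0.16 (SE). This call ended without WT 1 (camera adjusted p = 0.0506) and without WT 1 and WT 4, the libraries with airway transcripts (0.331). In the list mean S727A 4 (8.17 log2 CPM) lay above WT 2 (8.02), WT 3 (7.96) and WT 4 (8.15). Nuclear genes of respiratory complex I (median 0.06, 25 of 36 above 0, camera adjusted p = 0.0428) and of the other complexes (median 0.13, 33 of 40 above 0, camera adjusted p = 0.000483) passed as higher, with adjusted p of 0.549 and 0.473 with an estimated correlation. Both calls ended with offsets for transcript length and GC content, where the medians were -0.02 and 0.02 (camera adjusted p of 0.543 and 0.574). The complex I call also ended without S727A 1 (0.0862), S727A 2 (0.0976) or WT 3 (0.297), with the atrial marker covariate (0.13) and with the replicate block (0.0679). Ndufa11 was at 0.31 ± 0.11, Ndufb2 at 0.27 ± 0.10, Uqcr10 at 0.31 ± 0.09 and Uqcrh at 0.24 ± 0.08 (SE). Glycolysis (median 0.11, adjusted p = 0.0878), stress response (0.05, 0.246) and circadian genes (-0.14, 0.227) did not pass in camera, though the circadian list passed as lower without S727A 4 (0.0266). Their members of smallest p were Gapdh (0.31) and Pgk1 (0.27), Manf (0.32) and Atf4 (0.38), and Arntl (1.25) and Nr1d2 (-0.36), as log2 fold changes. None of the members in these 6 metabolic, stress and clock lists passed when adjusted over the list alone.

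Some lists of cell type markers also differed between the groups in camera. Macrophage markers fell (median -0.47, 12 of 16 below 0, camera adjusted p = 0.000263, 0.469 with an estimated correlation), 5 of them when adjusted over the list alone, among them Csf1r, the receptor for colony stimulating factor (-0.63 ± 0.13), and Cd163 (-0.80 ± 0.18, SE). The macrophage list mean differed by -0.357 log2 CPM, and by -0.209 without WT 3 (5.01), and S727A 2 (4.44) lay above WT 1 (4.36) and WT 4 (4.27). Smooth muscle and pericyte markers fell (median -0.28, 12 of 13 below 0, camera adjusted p = 9.77e-05, 0.469 with an estimated correlation), 4 of them over the list alone, with Acta2 at -0.80 ± 0.17 and Kcnj8 at -0.35 ± 0.09 (SE). In that list mean WT 3 (6.088 log2 CPM) lay below S727A 2 (6.125). Schwann cell and neuron markers (median -0.45, all 7 below 0, camera adjusted p = 0.0217) and atrial myocyte markers (-0.37, 9 of 11 below 0, adjusted p = 0.0469) also fell, with adjusted p of 0.469 and 0.549 with an estimated correlation. Log2 fold changes were -0.95 for Sox10 in the first of these lists and -0.77 for Kcnj3 and -0.73 for Stard10 in the other. The Schwann cell call ended without WT 2 (camera adjusted p = 0.0979) and with the atrial marker covariate (0.114). The atrial call ended without S727A 2 (0.145), WT 2 (0.28) or WT 4 (0.165) and without both libraries lacking Y-linked reads (0.122). It also ended with the Y-linked covariate (0.0543) and with the replicate block (0.0679). With the atrial marker covariate its camera adjusted p was 0.514. That covariate is the mean of this same list, so this setting removes most of its difference in advance.

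Markers of fibroblasts (median 0.07, camera adjusted p = 0.975), endothelium (0.01, 0.835), conduction cells (-0.32, 0.0918), adipocytes (-0.05, 0.434), red cells (0.28, 0.288) and epicardium (0.02, 0.485) did not pass. The conduction list passed as lower without WT 1 (camera adjusted p = 0.0218) or WT 3 (0.0353), the epicardial list as lower without S727A 1 (0.0175) and the red cell list as higher without both WT libraries with airway transcripts (0.00205). Within them, log2 fold changes were -1.14 for Scara5 and -0.35 for Ddr2, both fibroblast markers that passed over the list alone. They were 1.31 for Cldn5 and -0.20 for Tek, -0.41 for Tbx3 and -0.53 for Hcn4, -2.03 for Cfd and -1.49 for Pck1, 0.59 for Hbb-bs and 0.41 for Hbb-bt, and -0.65 for Upk3b and -0.67 for Muc16. The median and mean of the fibroblast list (0.07 and -0.01) and of the epicardial list (0.02 and -0.10) differed in sign. Lists with under 5 tested members were read as summed CPM, S727A against WT: neutrophil genes 6.25 against 6.31, lymphocyte genes 6.43 against 6.09, skeletal muscle genes 76.1 against 46.2 and lung genes 1.86 against 29.7. The lung signal came from WT 1 and WT 4, where Scgb1a1 had 863 and 344 counts against at most 12 elsewhere.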

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

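All tests of this part were chosen after the results they concern were seen, except the counts over splits of the libraries, whose predictions were written before they were run. The prediction for exchanged labels was also written before its test was run. That test uses the window around Stat3, which was chosen after the data were seen.

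Of 224 groups of 4 libraries, for the named genes and the list means, 15 (6.7%) held a library far from the others by Dixon's ratio of gap to range, where chance gives about 1 in 20. S727A 4 accounted for 5: Nppb (8.71 log2 CPM, others 9.97 to 10.09), Synpo2l (8.76, others 9.66 to 9.83), the matrix list (5.91, others 6.52 to 6.60), Armh4 (2.88, others 2.46 to 2.51) and Sfr1 (5.89, others 5.82 to 5.83). S727A 1 accounted for 4: Ndufa11 (8.99, others 8.66 to 8.71), Ddr2 (4.83, others 5.13 to 5.20), the glycolysis list (8.66, others 8.55 to 8.56) and the adipocyte list (4.47, others 3.68 to 3.77). WT 3 stood apart for Etv4 (1.24, others 0.36 to 0.41) and Acta2 (7.16, others 7.89 to 7.99). WT 4 did so for the circadian list (5.89, others 5.79 to 5.80) and the endothelial list (6.87, others 6.69 to 6.71), WT 1 for Manf (4.33, others 4.62 to 4.67) and WT 2 for Smpx (7.54, others 7.64 to 7.65).

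Chance was not excluded for the counts of calls. Of the 35 splits of the 8 libraries into 4 and 4, 2 including the real one gave at least as many genes as the real 6 higher and 13 lower, taken by direction or together. The other split called 214 genes, its larger direction holding 126, and every remaining split called 0. DESeq2 called 513 genes in the real split and 903 in that other one, again 2 of 35. For lists passing camera, 2 of 35 splits reached the real 17, the highest other giving 19. Every other split also passed lists, from 2 to 19. Splits with 2 libraries of each genotype on each side, which hold no genotype contrast, passed 2 to 14 lists. A camera pass therefore does not by itself mark a difference between genotypes here.

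The split with 214 genes exchanges S727A 4 and WT 3, and points to a structure of the samples that crosses genotype. Its calls include 14 matrix, 5 cell-cycle and 3 hypertrophy genes and 0 of the 19 called under the labels as given. This split sets S727A 4 and WT 4, which almost lack Y-linked reads, on the same side. WT 1 and WT 4, with airway transcripts, are also on that side. The labels as given separate S727A 4 from WT 4, but not WT 1 from WT 4. How far these traits contribute to the 214 calls was not tested. Whether the labels of S727A 4 and WT 3 were exchanged stays open. Genes within 2 Mb of Stat3 were enriched at unadjusted p under 0.01 with the labels as given (odds ratio 3.39, 95% interval 1.79 to 6.02). They were not enriched after the exchange (0.982, 0.381 to 2.13, Fisher's exact p = 1). That window was chosen for its excess under the labels as given, so the comparison favours these labels and cannot decide. The matrix list rose above the fibroblast list by 0.724 log2 CPM, beyond the pooled SD of 0.404. This argues only against more fibroblasts with unchanged levels of the listed markers as the source of the matrix signal. Of the 12 fibroblast markers 7 had a fold above 0 and 5 below, so fibroblasts with altered marker levels stay open. An uneven response to constriction between animals, with WT 3 responding strongly and S727A 4 weakly, stays open and cannot be told apart from a genotype effect here: the exact permutation p of the 3 list means was 0.0571 at most, and pressure gradients were not analysed here. A genotype effect on remodelling therefore also stays open.

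The excess of small p-values around Stat3 is the second pattern. Chance position is not excluded, because the width and cut-off were chosen after the excess was seen. At these settings 0% of 3484 windows of the same width elsewhere with at least 50 genes reached 17.86%, the highest reaching 16.67%. The margin is small, these windows overlap, and the genes counted near Stat3 include the proliferation genes named below. Transcript length and GC content are argued against, as 16.67% of the genes within 2 Mb stayed under 0.01 after the offsets, against 5.91% of other genes. A candidate explanation is DNA linked to the mutant allele, such as a flanking segment of another strain, which stays open. From 2 to 5 Mb, without the genes that prompted this test, the odds of a small p were 2.17 times those beyond 20 Mb on the same chromosome, which did not pass (Fisher's exact p = 0.0776). Sequence variants were not analysed here, a local effect of the allele stays open, and Top2a, Brca1 and Cdc6 in this window are proliferation genes that go with the first pattern. Etv4, named above in the ERK feedback list, is also among the genes counted in this window.

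The third pattern is airway RNA in WT 1 and WT 4. The sum of 7 airway secretory genes (Scgb1a1, Scgb3a1, Scgb3a2, Cyp2f2, Bpifa1, Bpifb1 and Muc5b) was 2075 counts in WT 1 and 1043 in WT 4, against 3 to 24 in every other library, so a fragment of bronchus may have been taken with these hearts. Whether it is the source of any of the 13 lower genes, which include Cbr2, stays open. S727A lay below WT 2 and WT 3 by a median log2 difference of -1.013 (SD over genes 0.548). Against WT 1 and WT 4 the median was -1.12 (0.497), a similar size. Each gene was called with WT 2 and WT 3 above every S727A library, so the selection fixes the sign. A call also favours genes with similar values in all WT libraries, so this excludes nothing. Without WT 1 and WT 4 edgeR called 0 genes, with 1307 at an unadjusted p under 0.05, in a fit of 4 against 2 libraries. For this pattern no biological explanation was tested.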

How the results depend on the processing

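Added after seeing the data were the fits that leave out 2 libraries, the length and GC offsets, the robust and the 0.05 settings below and the exact permutation of list means. Against 6 genes higher and 13 lower in the main analysis, no filter gave 11 and 16 and limma voom 0 and 6 (2321 genes at unadjusted p under 0.05). The robust form of voom gave 3 and 11, the atrial covariate 3 and 8, and limma trend on FPKM 1 and 5. DESeq2 gave 273 and 240, or 285 and 248 with filtering at 0.05. Of the 19 calls, all were kept by DESeq2, 6 by voom and 17 by the length and GC offsets. Leaving out both libraries lacking Y-linked reads gave 107 and 135, and both WT libraries with airway transcripts 0 and 0. Leaving out each library in turn gave 0 to 297 genes higher and 0 to 320 lower, and the 19 genes had the same sign in every setting. These 19 genes all separated the libraries of the groups, so their signs were nearly fixed in advance and add no support. With 0 calls, 1762 genes (without S727A 1), 1704 (without S727A 3) and 1576 (without WT 1) had an unadjusted p under 0.05 in edgeR. The replicate block gave 0 and 2 (2074 genes at unadjusted p under 0.05). Residuals of same-numbered libraries correlated at -0.052, -0.102, 0.065 and 0.071, against -0.253 to 0.178 for other pairs between the groups. These few values cannot decide whether the numbers pair the libraries, and replicate 4 almost lacked Y-linked reads in both groups. Against 17 lists passing, 0 passed with an estimated correlation (1 at unadjusted p under 0.05), 0 in fry (7) and 0 by exact permutation of list means (1), 12 with the atrial covariate, 15 with the replicate block, 14 with the length and GC offsets, and between 13 and 19 with single libraries left out, which kept 13 to 17 of the 17. Fold changes ran with transcript length across genes (Spearman rho -0.186, genes not being independent), the median being 0.07 in the shortest group of 5 and -0.06 in the longest. Stat3 ran from -0.34 to -0.22 and never passed (adjusted p 0.0597 to 0.494). Of the other named genes only Pck1 changed sign, to 0.0302 without the libraries lacking Y-linked reads. The cause of these changes was not tested. Leaving out a library raised the number of calls in some fits and lowered it in others. At this depth and spread, simulated changes of 1.5-fold were recovered in 39.8% of genes, so smaller effects were mostly not detectable. The simulated genes were drawn independently, without the structure between libraries seen here, so these shares may overstate the recovery in the real data.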

Other observations

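The genes below were chosen after their values were seen. Macrophage genes looked at in this way went both ways, and they were not tested as a group of their own. Of them Mrc1, C1qa, Cd68, Lyve1, Mpeg1, Trem2, Ccr2 and Adgre1 are members of the macrophage list tested above. Log2 fold changes were -1.29 ± 0.39 for Timd4, -0.99 ± 0.23 for Folr2, -0.81 ± 0.18 for F13a1, -1.10 ± 0.21 for Siglec1, -0.55 ± 0.15 for Mrc1, -0.50 ± 0.20 for C1qa, -0.43 ± 0.14 for Cd68 and -0.40 ± 0.18 for Lyve1 (SE). They were 0.21 ± 0.24 for Mpeg1, 0.27 ± 0.32 for Trem2 and 0.12 ± 0.36 for the monocyte receptor gene Ccr2 (SE). None passed over all genes, with edgeR adjusted p from 0.0863 for Siglec1 to 0.899 for Ccr2. Adgre1 was at 6.26 log2 CPM in WT 3 and between 3.64 and 4.41 in the other 7 libraries.

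Beside the rise of Jchain, other genes of plasma and B cells did not pass: Mzb1 was at -0.20 ± 0.38, Cd79b at -0.27 ± 0.34, Irf4 at -1.52 ± 0.36 and Sdc1 at 0.57 ± 0.17 (log2 fold change, SE). Immunoglobulin genes were not analysed here. Just above the threshold were Ehd4 (0.55 ± 0.09, edgeR adjusted p = 0.0503) and Fam189a2 (0.57 ± 0.10, 0.0527), both higher in all S727A libraries.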
